A study of Homo sapiens with 8 samples.

How the data were processed

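Total RNA from KYSE70 and KYSE450 cells at passages 5 to 10 was sequenced, per the labels, in 8 libraries: overexpression, its control, knockdown and its control, each in both lines. The deposited files give 1 value per gene and library. The submitters' processing notes name TopHat2 2.0.9, HTSeq 0.6.1 and the genome build hg19, without their roles; the annotation, the filters and the strand setting are not given in the sources used here. No header or label names the unit, which was taken from the values: the deposited values behave as FPKM, that is, reads per kilobase of gene scaled to the library's total reads. Within each of the 30872 genes above 0 in 2 or more libraries, all values were whole multiples of 1 step after 1 factor per library, within 0.02 of a whole number. Whether these are reads or fragments is not given in the sources used here, and they are called reads throughout. The whole reads recovered in this way made up 99.8% of each library's total and ran from 26402503 to 37938581 per library. At these depths, 1 read in a gene of 1 kb is worth 0.0263 to 0.0378 FPKM. Recovered reads cover counting error only, because reads without molecular identifiers are not independent molecules.

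The files list 48162 genes, of which 45342 identifiers occur in GENCODE release 29 on GRCh38; gene type and coordinates come from that release, and gene names from the files. Groups came from the titles. Same-numbered libraries come from the same cell line, so the numbers pair the libraries. Correlations between libraries of the same line were 0.949 to 0.996 in KYSE70 and 0.955 to 0.994 in KYSE450, against at most 0.847 between the lines. Genes with a mean FPKM of at least 1 were kept, 14311 in all, and log2(FPKM + 1) was fitted with limma 3.58.1 (trend) in R 4.3.3. The model held a term for each of the 4 pairs of treated library and control plus overexpression and knockdown terms, which leaves 2 residual degrees of freedom, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The design, written before the data were examined along with the gene lists, the rule for named genes and most of the alternatives, assumed counts; because the deposited values are FPKM, its written fallback for FPKM was used. Cell line was tested without a block and the controls with a model of cell line and group.

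A total of 42 gene lists, of pathways, of other cell types and of RNA quality, were written, and the 39 with at least 3 members measured were tested. The main test was camera with a preset correlation of 0.01, and camera with an estimated correlation and fry were alternatives; adjusted p-values run over the lists of 1 comparison. Fry asks whether a list moves one way on balance, or whether its members change in either direction, and compares it with no other genes. The rule for named genes takes, per comparison, up to 10 called genes in each direction with the same sign in all pairs. It fills up with genes of the same sign ranked by the smaller change of the lines, described by value only. It adds up to 3 members per list by p and always MMP3, MMP10, NSUN2 and BPTF; for the cell lines and the controls it takes up to 5 called genes in each direction. MMP3 lay below the filter and was not tested, and 0 genes were called between the controls. The rule's minimum on CPM was applied to FPKM. List members are named for the lists that camera called and, under knockdown, for those with a member passing when adjusted over the list alone; which lists have members named was decided after the results were seen. Some members that this takes are not reported here.

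The limma fits were tested on simulated data drawn with the spread of the real pairs, with 200 changed genes in each of 5 draws. At 2-fold, 48.4% of changed genes were recovered with the spread of the overexpression pairs and 46.6% with that of the knockdown pairs; at 4-fold, 87.0% and 88.4%. False calls averaged 0.4 and 7.6 per draw. Every simulated gene had the same spread within a manipulation, and a changed gene had the same change in both lines. Real genes need not share either, so the shares recovered can be too high for the real data. The alternatives changed the pseudocount (0.1), the filter (none, or a mean FPKM of at least 5), the scaling, the block, the libraries in the fit, the threshold and the list test, and left out each library in turn. The comparison of knockdown levels with the overexpression control, the number of list members given by the share of all genes with that direction in every pair, and the listing of the mitochondrial list beside the called ones were added after the results were seen. Added after the data were seen were voom on recovered reads, median-ratio scaling, quantile normalization, a robust prior, the lists without knockdown replicate 1, subtraction of a trace of the other line, and removal of trends on GC content and exon length by loess with a span of 0.3. The trace is the median share, over markers at 50 FPKM or more in 1 line and at most a 100th of that in the other, of the level in the library of the same group; a marker's own share is left out. Length and GC content were known for 97.2% of the tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Small structured RNAs, leukocyte markers and cancer-testis antigens had too few measured members to be tested as lists.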

Results

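RNA sequencing was used to profile the human esophageal squamous cell carcinoma lines KYSE70 and KYSE450 after the long noncoding RNA NMR was overexpressed or knocked down. The series holds 8 libraries in 4 groups of 2 libraries each, with 1 library per cell line in every group. Overexpression used a transfected plasmid, knockdown used lentivirus made in HEK 293T packaging cells, and each had its own control. Replicate 1 is KYSE70 and replicate 2 is KYSE450 throughout, so n = 2 cell lines stands behind each treated-against-control value and a line is never replicated within a group. Reads, or fragments, since the sources used here do not say which, were recovered from the FPKM values and came to 31419382 and 27052135 in the overexpression controls and 29957620 and 29205870 with overexpression, KYSE70 first in each case. They came to 26414477 and 37938581 in the knockdown controls and 26402503 and 29199741 with knockdown. The labels do not say that the libraries came from separate cultures beyond the cell line, so p-values measure only the spread between these libraries. For overexpression and knockdown that spread is how far the changes differ between the lines. Cell line separated the libraries along the first principal component, with 77.0% of the variance. The plasmid and lentiviral arms parted along the second, with 11.2%. No listed gene carries the name NMR, and no reference table used here gives that name, so the level of the target was not analysed here and neither manipulation was checked on its target.

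The overexpression comparison asks which genes move when NMR is raised. Among the genes with the same direction in both lines, GPNMB, a transmembrane glycoprotein gene, had the highest log2 fold change of the named genes, 1.32 (SE 0.27, n = 2 pairs), from 8.07 to 15.9 FPKM in KYSE70 and from 13.3 to 46.4 FPKM in KYSE450. IGFBP5, which encodes an insulin-like growth factor binding protein, stood at 1.26 (SE 0.36), from 0.81 in KYSE70 and 1.71 in KYSE450. NREP stood at 0.61 (SE 0.16), the vault particle gene MVP at 0.63 (SE 0.17) and ZBED2 at 0.62 (SE 0.24). With knockdown, GPNMB (1.18 and 0.31, KYSE70 first), IGFBP5 (3.26 and 1.76) and NREP (0.77 and 0.68) were higher in both lines as well. These 3 genes thus did not move in opposite directions with the manipulations. MVP and ZBED2 had opposite signs in the knockdown pairs. On the lower side were the fibrillin gene FBN1 at -0.55 (SE 0.17), RPP21, a subunit of ribonuclease P, at -0.61 (SE 0.19), and VWA5B2 at -0.61 (SE 0.31). The remaining genes named by the rule were mostly noncoding RNAs and pseudogenes of low level, such as RP11-159F24.5 at 0.97 (SE 0.18) and the pseudogene UBE2FP1 at -0.72 (SE 0.17), whose reads can be shared with their parent genes. The fitted changes are on the log2(FPKM + 1) scale, which understates the change of low genes. None of the 14311 genes tested passed an adjusted p of 0.05 in limma (smallest adjusted p 1), 148 had an unadjusted p under 0.05 where chance gives 716, and limma's voom on the recovered reads also called 0. The chance count assumes that all pairs vary alike. The fit takes 1 spread for both manipulations, while that of the real pairs was 0.098 for overexpression and 0.257 for knockdown, in log2. P-values thus tend to be too large for overexpression and too small for knockdown, and 716 holds for neither. A fit of the 4 overexpression libraries alone, with 1 residual degree of freedom, called 12 genes, 9 higher and 3 lower, GPNMB, IGFBP5, MVP and VWA5B2 among them. The rule named these genes from the same libraries, so their calls add no support. Leaving out overexpression control replicate 1 or overexpression replicate 1 gave 3 calls each, where the KYSE450 overexpression pair alone remains and is assumed to vary like the knockdown pairs.

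Squamous and adhesion genes stood higher with overexpression. Of 17 measured genes of basal squamous identity, 16 had a fitted change above 0 and 15 were higher in both lines, with a median of 0.38, or 0.21 in KYSE70 and 0.44 in KYSE450. With knockdown 8 of the 17 were higher in both lines too, where the share of all genes gives 4.61. Camera did not call the list for higher against lower NMR (adjusted p 0.191). The integrin gene ITGB4 stood at 0.45 (SE 0.18). The keratin gene KRT16 stood at 0.89 (SE 0.32), from 0.18 in KYSE70, where it lay near the floor, and 1.61 in KYSE450. Integrin and laminin genes, a list that shares members with the first, had a median of 0.23 with 15 of 16 above 0, and squamous differentiation genes a median of 0.29 with 6 of 9 above 0 (0.15 and 0.22 in the lines), among them SPRR1A at 0.55 (SE 0.17) and TGM1 at 0.59 (SE 0.18). Of the cell cycle genes, 24 of 25 mitotic and 25 of 25 replication genes had a fitted change below 0, with medians of -0.11 and -0.07, and 15 of 25 in each list were lower in both lines, where the share of all genes gives 6.91. The mitotic median was -0.01 in KYSE70 and -0.18 in KYSE450, and the replication median -0.03 and -0.10. CCNA2 stood at -0.25 (SE 0.15), from -0.08 and -0.42. The camera test, with a preset correlation of 0.01 between genes, called 14 of 39 lists, 10 up and 4 down. The adjusted p was 7.22e-13 for basal squamous identity, 2.11e-09 for integrins and laminins and 0.000499 for both the squamous differentiation and the mitotic genes. None held with an estimated correlation: the adjusted p was 0.560 with an estimated correlation for basal squamous identity and for integrins and laminins, 0.624 for squamous differentiation, 0.682 for mitotic genes and 0.764 for replication genes, and fry called 0 lists. No member of these lists passed over all genes or when adjusted over the list alone.

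The other lists called by camera under overexpression had smaller or less even medians. NRF2 targets, which answer oxidative stress, stood at -0.17 with 17 of 18 below 0, from a median of -0.02 in KYSE70 and -0.24 in KYSE450, and AKR1C1 at -0.07 and -0.65 in the lines. The p53 targets stood at 0.12 with 16 of 21 above 0, and CDKN1A among them at 0.08 in KYSE70 and 1.55 in KYSE450. With trends on GC content and length removed, the p53 median was 0.12, from 0.05 in KYSE70 and 0.11 in KYSE450. HLA class I genes stood at 0.11 with 10 of 14 above 0, from 0.03 in KYSE70 and 0.21 in KYSE450 (HLA-C 0.33, SE 0.20). Matrix metalloproteinases and their inhibitors had a median of 0.15, from 0.01 in KYSE70 and 0.23 in KYSE450 (MMP14 0.35, SE 0.16, from 0.14 and 0.56 in the lines). NOTCH pathway genes stood at 0.05, with 0.09 in KYSE70 and 0.17 in KYSE450, and HES2 at 0.02 and 1.07 in the lines. Epithelial junction genes stood at 0.04, with 0.06 in KYSE70 and 0.13 in KYSE450 (JUP 0.37, SE 0.16, from 0.21 and 0.53 in the lines). Oncogenes of esophageal amplicons stood at 0.07, from 0.15 in KYSE70 and 0.00 in KYSE450 (TP63 0.41, SE 0.28). Integrated stress response genes had a median of 0.19, but -0.04 in KYSE70 against 0.36 in KYSE450. The 3 genes of the metallothionein list had a median of -0.30, with 0.07 in KYSE70 and -0.51 in KYSE450. The adjusted p lay between 0.624 and 0.682 with an estimated correlation for these 9 lists, and the NOTCH call was lost once trends on GC content and length were removed (adjusted p 0.0589 in camera), with its median at 0.052 before and after.

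**Figure D1:**
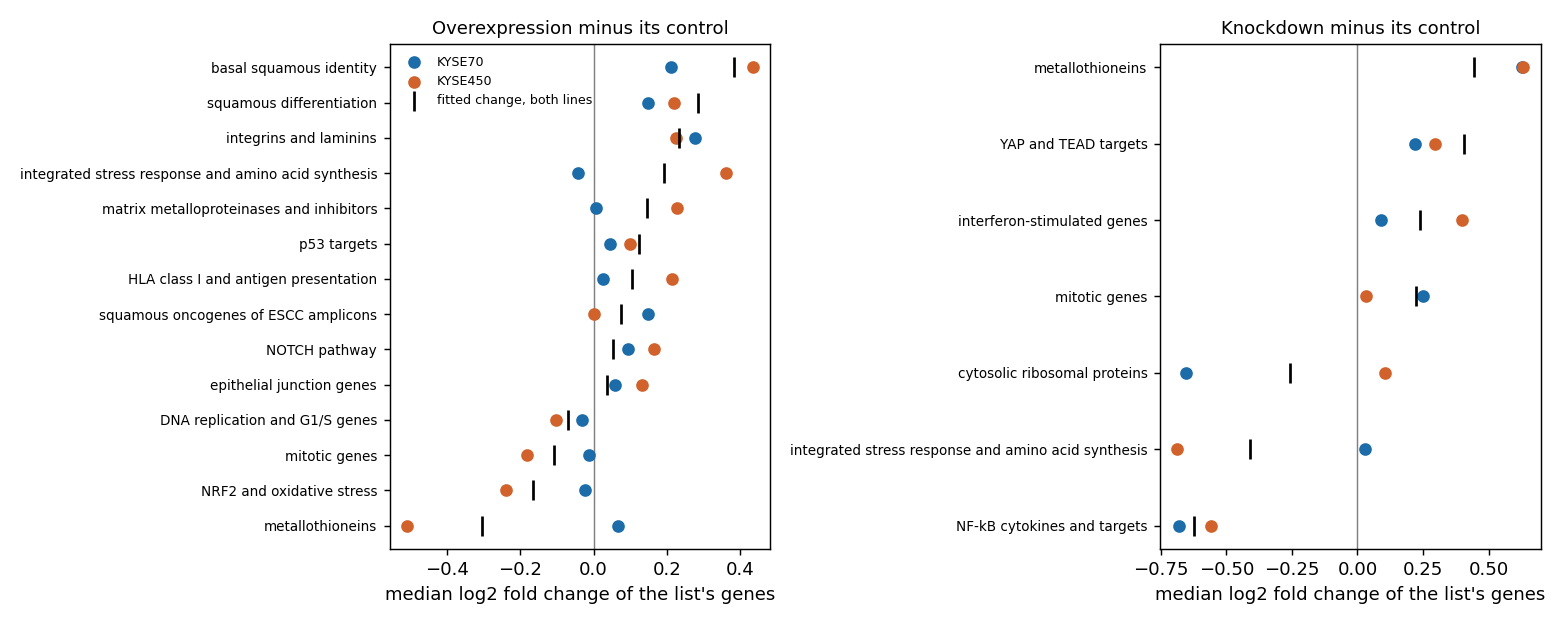
Median log2 fold change, on the log2(FPKM + 1) scale, of the gene lists called by camera with its preset correlation under overexpression (left) and knockdown (right). Points give the median within the KYSE70 pair (blue) and the KYSE450 pair (orange), 1 treated and 1 control library each, and bars the median of the fitted changes; NF-kB genes lie at -0.68 and -0.56 in the knockdown pairs, while integrated stress response and ribosomal protein genes lie on opposite sides of 0 in the lines.

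The knockdown comparison asks which genes move when NMR is lowered. EDN2, the gene of the vasoconstrictor peptide endothelin 2, had the highest log2 fold change of the named genes, 2.51 (SE 0.19, n = 2 pairs, adjusted p 0.0587 in limma), from 4.27 to 34.0 FPKM in KYSE70 and from 0.674 to 7.21 FPKM in KYSE450. IGFBP5 stood at 2.51 (SE 0.36), the tetraspanin gene TSPAN12 at 1.79 (SE 0.17), VAV3 at 1.53 (SE 0.24), the collagen gene COL5A1 at 1.42 (SE 0.21), CDK14 at 1.25 (SE 0.17) and SNX10 at 1.15 (SE 0.15). The interferon-induced genes DDX60 and IFIT1 stood at 1.49 (SE 0.17) and 1.13 (SE 0.18). On the lower side were GDF15, a stress-induced cytokine gene, at -1.76 (SE 0.31), the EGFR ligand genes HBEGF at -1.49 (SE 0.22) and AREG at -1.28 (SE 0.16), the matrix glycoprotein gene TNC at -1.44 (SE 0.18), the cyclin gene CCND3 at -1.40 (SE 0.18), FGF21 at -1.28 (SE 0.20) and the mitochondrial gene MT-CYB at -1.22 (SE 0.24). In KYSE450 the levels of several of these genes with knockdown lay between those of the knockdown control and the overexpression control, or near the latter: EDN2 stood at 10.9 FPKM in the overexpression control against 0.674 and 7.21 in the knockdown control and with knockdown, IGFBP5 at 52.8 against 0.285 and 3.36, TSPAN12 at 9.91 against 1.86 and 7.84, DDX60 at 6.43 against 1.43 and 6.25, and AREG at 1.54 against 40.1 and 15.4. Of the 20 genes named by the rule, 16 lay nearer to the overexpression control with knockdown than in the knockdown control in KYSE450 and 8 in KYSE70, against 60.4% and 32.9% of all 14311 genes. Of the genes at least 2-fold apart, with no minimum on reads, this held for 117 of 137 (85.4%) in KYSE450 and 144 of 775 (18.6%) in KYSE70. Both sets were chosen by their difference from the knockdown control, which enters the distances as well, and the shares were not tested. With 1 library per line and group, a response to knockdown cannot be told apart from a deviation of the knockdown control in either line. EDN2 lies on chromosome 1 from 41478775 to 41484673, IGFBP5 on chromosome 2 from 216672105 to 216695525 and TSPAN12 on chromosome 7 from 120787320 to 120858402, in GRCh38 coordinates of GENCODE release 29; all 3 are annotated as protein coding.

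No gene passed an adjusted p of 0.05 in limma in the knockdown comparison. An unadjusted p under 0.05 was reached by 1794 genes, where chance gives 716 if all pairs vary alike. The knockdown pairs varied more than the overexpression pairs that share their spread in the fit (0.257 against 0.098 in log2). The excess can therefore come in part from the shared spread. Voom on the recovered reads called 4 genes, all higher: EDN2, IGFBP5, TSPAN12 and TIMP3, and a pseudocount of 0.1 called the first 3; TIMP3 was named after its values were seen. The 4 knockdown libraries fitted alone, with 1 residual degree of freedom, called 37 genes, 23 higher and 14 lower, which included 19 of the 20 genes named by the rule. The rule chose these genes from the same libraries for large changes of the same sign, so the overlap is built in and adds no support. Some of the 37 were carried by 1 line, such as SEMA3C at 2.79 in KYSE70 and 0.31 in KYSE450. The count rested on single libraries: it was 582 without knockdown control replicate 1, 4832 without knockdown control replicate 2, 580 without knockdown replicate 1 and 4833 without knockdown replicate 2, where the remaining knockdown pair is assumed to vary like the overexpression pairs. The KYSE70 knockdown library stood apart in several measures, which go with every KYSE70 knockdown value given here. Mitochondrially encoded genes took 8.63% of its FPKM sum against 3.84% to 5.75% in the other libraries. Across genes, the log2 fold change of the KYSE70 knockdown pair had a Spearman correlation of -0.483 with GC content, against 0.042 in the KYSE450 knockdown pair; genes are not independent replicates.

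**Figure D2:**
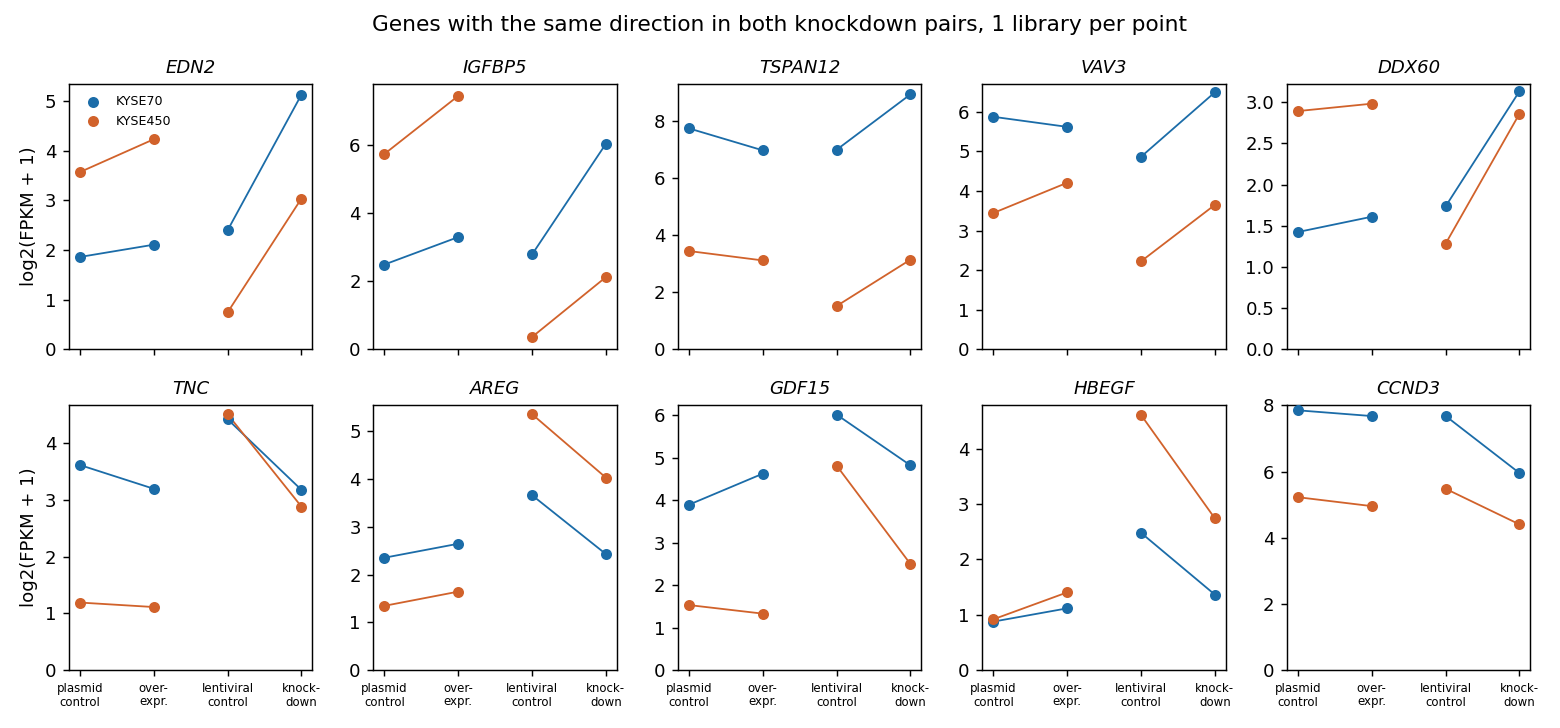
Level, as log2(FPKM + 1), of 10 genes with the same direction in both knockdown pairs. Each point is 1 library, lines join a treated library with its control in KYSE70 (blue) and KYSE450 (orange), and there are no error bars because a line has 1 library per group; EDN2 lies 2.73 and 2.29 above its control in the knockdown pairs and TNC at -1.25 and -1.63 from it.

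NF-kB cytokines and targets were lower in the knockdown libraries of both lines. Of 17 measured members, 15 had a fitted change below 0 and the median was -0.62, with -0.68 in KYSE70 and -0.56 in KYSE450. With GC and length trends removed it was -0.51, from -0.45 and -0.58. Adjusted over the list alone, 8 of the 17 fell, against 0 over all genes. They include TNFAIP2 at -1.01 (SE 0.18), the cytokine gene LIF at -1.13 (SE 0.22) and the chemokine gene CXCL3 at -0.89 (SE 0.19). Camera with the preset correlation called the list (adjusted p 1.16e-05), and its adjusted p was 0.794 with an estimated correlation. Of the EGF receptor family and its ligands, AREG and HBEGF fell and EGFR rose, at 0.67 (SE 0.19), when adjusted over the list alone, and camera did not call the list (adjusted p 0.219). Of the p53 targets, 6 of 21 passed when adjusted over the list alone, 3 in each direction, with GADD45A at -0.95 (SE 0.15), GDF15 at -1.76 and MDM2, the ubiquitin ligase that limits p53, at 0.83 (SE 0.15). Between the knockdown and the overexpression control GADD45A differed by 1.71 and 1.615, GDF15 by 2.125 and 3.29 and MDM2 by -0.61 and -0.94, KYSE70 first. For GADD45A, GDF15 and MDM2 a response thus cannot be told apart from a deviation of the knockdown control. Of the ERK pathway output genes 3 of 21 passed adjusted over the list alone, with EGR1 at 1.09 (SE 0.23), ETV5 at -1.02 (SE 0.22) and SPRY4 at -0.89 (SE 0.21). Neither list was called by camera, at adjusted p 0.422 and 0.0990.

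Targets of YAP and TEAD and interferon-stimulated genes had medians above 0 with knockdown. Of 13 YAP and TEAD targets 11 were above 0, with a median of 0.41. With GC and length trends removed the median was 0.27, from 0.27 in KYSE70 and 0.26 in KYSE450. When adjusted over the list alone 3 rose: AMOTL2 at 0.70 (SE 0.17), AJUBA at 0.55 (SE 0.14) and CYR61 at 0.67 (SE 0.19). In log2, KYSE70 first, AJUBA differed by -0.87 and -1.40 between the knockdown and the overexpression control. CYR61 differed by -0.66 and -0.34 and AMOTL2 by 0.05 and -0.58. A response of AJUBA or CYR61 thus cannot be told apart from a deviation of the knockdown control in either line. Of 28 interferon-stimulated genes 21 were above 0, with a median of 0.24, from 0.09 in KYSE70 and 0.40 in KYSE450, and DDX60 and IFIT1 rose when adjusted over the list alone. Mitotic genes had a median of 0.22 with 20 of 25 above 0, from 0.25 in KYSE70 and 0.03 in KYSE450 (ASPM 0.64, SE 0.16), and MT2A at 0.83 (SE 0.16) was the 1 metallothionein that rose when adjusted over the list alone. Ribosomal protein genes had a median of -0.66 in KYSE70 and 0.10 in KYSE450. The sum of their FPKM was 31831 in the KYSE70 knockdown library and 49681 in its control. Integrated stress response genes had a median of 0.03 in KYSE70 and -0.69 in KYSE450 (ATF4 -0.63, SE 0.15). Camera called these lists and the NF-kB list, 7 of 39, with 4 up and 3 down. All 7 were lost at adjusted p between 0.794 and 0.831 in camera with an estimated correlation. Without knockdown replicate 1 the KYSE450 pair alone remains and is assumed to vary like the overexpression pairs. List calls from that fit are therefore not given. Fry called 0 lists for a move in one direction and 7 for change in either direction, the NF-kB, interferon, EGF receptor and p53 lists among them.

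Several lists held single genes that passed when adjusted over the list alone under knockdown, without a call in camera. Among the squamous differentiation genes the keratin genes KRT4 at 1.07 (SE 0.16) and KRT13 at 1.13 (SE 0.20) rose and KRT10 at -0.77 (SE 0.24) fell. In KYSE450, KRT4 stood at 80.1 FPKM in the overexpression control, 1.36 in the knockdown control and 3.98 with knockdown. KRT13 stood at 5525, 2139 and 3796 in the same order. With knockdown, KRT4 and KRT13 thus lay between the controls in KYSE450, while in KYSE70 they lay above both controls. TIMP2 at 0.73 (SE 0.16) and TIMP3 at 1.12 (SE 0.30) rose among the metalloproteinases and inhibitors. TNC fell among the mesenchymal genes. NDRG1 at 1.07 (SE 0.18) and ANGPTL4 at 1.15 (SE 0.26) rose among the hypoxia genes and MSMO1 at 1.24 (SE 0.23) among the cholesterol genes. MT-CYB, MT-ND6 at -0.98 (SE 0.21) and MT-ND5 at -0.90 (SE 0.22) fell among the 13 mitochondrial messenger RNAs, whose median was 0.33 in KYSE70 and -0.25 in KYSE450. BIRC3 at -0.68 (SE 0.16), BIK at -0.63 (SE 0.16) and HRK at -0.70 (SE 0.20) fell among the apoptosis regulators, while BIRC2, named after its values were seen, rose at 0.63 (SE 0.18). Some of these values were uneven between the lines, KYSE70 first: TIMP3 stood at 1.80 and 0.44, KRT10 at -1.28 and -0.26, ANGPTL4 at 0.66 and 1.64, HRK at -0.41 and -0.98 and BIRC2 at 0.95 and 0.32. The same held for EGR1 at 1.51 and 0.67, ETV5 at -0.55 and -1.49, SPRY4 at -1.23 and -0.55, EGFR at 0.92 and 0.42, AMOTL2 at 0.96 and 0.43 and COL3A1 at 2.25 and 0.89. Of the fibroblast markers COL3A1 at 1.57 (SE 0.31) rose and COL1A1 stood at 0.17 (SE 0.14); neither the fibroblast list (adjusted p 0.236) nor the packaging cell list (adjusted p 0.780) was called by camera.

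The responses of the lines were compared pair by pair, with 1 treated and 1 control library in each and without a test within the pair. At least 2-fold changes, in genes with 10 or more reads in 1 of the libraries, numbered 26 for overexpression in KYSE70 and 48 in KYSE450. For knockdown they numbered 768 in KYSE70, 239 higher and 529 lower, and 136 in KYSE450, 83 higher and 53 lower. For overexpression, 0 genes changed 2-fold the same way in both lines and 1 changed in opposite directions. For knockdown, 21 changed the same way, 12 higher where independent lists give 1.39 and 9 lower where they give 1.96, while 8 changed in opposite directions where 3.95 are given. Across genes the log2 fold changes of the lines had a Pearson correlation of 0.128 for knockdown and 0.039 for overexpression. Overexpression and knockdown, which share no library, had a correlation of 0.101 across genes for the fitted changes.

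A further comparison set the libraries meant to hold more NMR (overexpression and knockdown control) against those meant to hold less, within each pair. NUPR1, a stress-induced chromatin protein gene, stood at 1.23 (SE 0.32, n = 4 pairs), the potassium channel gene KCNMA1 at 0.83 (SE 0.21), AREG at 0.79 (SE 0.21), GADD45A at 0.63 (SE 0.15) and the nucleoside transporter gene SLC29A4 at 0.47 (SE 0.11), each higher in all 4 pairs. TSPAN12 at -1.17 (SE 0.25), COL3A1 at -0.99 (SE 0.29), the metallothionein gene MT2A at -0.63 (SE 0.13), TSPAN7 at -0.46 (SE 0.14) and DCLK1 at -0.44 (SE 0.11) were lower in all 4. The rule takes only genes with the same sign in all 4 pairs, so that agreement is built in. Of all tested genes, 4.9% were higher and 6.5% lower in all 4 pairs. NUPR1 changed by 0.41 and 2.31 with overexpression and by -1.82 and -0.40 with knockdown, KYSE70 first. The COL3A1 value rested most on the KYSE70 knockdown pair. It changed by -0.54 and -0.29 with overexpression and by 2.25 and 0.89 with knockdown, KYSE70 first. Limma called 0 genes (smallest adjusted p 0.922), 422 had an unadjusted p under 0.05 where chance gives 716, and voom called 0. Camera called 7 of 39 lists. Integrated stress response genes at a median of 0.35, NF-kB genes at 0.33, ERK output genes at 0.17 and ribosomal protein genes at 0.09 were up, and mitotic genes at -0.16, metallothioneins at -0.33 and NRF2 targets at -0.17 were down. Members that went that way in all 4 pairs numbered 3 of 19 integrated stress response genes, where the share of all genes gives 0.93, 3 of 17 NF-kB genes (0.83 given) and 3 of 21 ERK output genes (1.03 given). They numbered 0 of 42 ribosomal protein genes (2.05 given), 8 of 25 mitotic genes (1.62 given), 1 of 3 metallothioneins (0.19 given) and 3 of 18 NRF2 targets (1.16 given). The integrated stress response median comes from KYSE450, at 0.36 with overexpression and -0.69 with knockdown, against -0.04 and 0.03 in KYSE70. The NF-kB median with overexpression was 0.14 in KYSE70 and -0.01 in KYSE450. Ribosomal protein medians had opposite signs in the lines, at -0.16 and 0.05 with overexpression and -0.66 and 0.10 with knockdown. The knockdown controls count as higher NMR here. Integrated stress response, NF-kB and ERK output genes also stood higher in them than in the overexpression controls, and mitotic genes lower. A deviation of the knockdown controls can therefore enter the medians of these lists. None of the 7 calls held, at adjusted p between 0.602 and 0.918 with an estimated correlation; without knockdown replicate 1 camera called 15. Adjusted over the list alone, AREG and HBEGF rose among the EGF receptor genes, and MT2A and COL3A1 fell among the metallothioneins and the fibroblast markers.

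The knockdown control was also set against the overexpression control, which compares lentiviral with plasmid delivery and any batch between them. NF-kB genes had a median log2 difference of 1.78 with 16 of 17 above 0, among them PTGS2, the gene of an inducible cyclooxygenase, at 3.04 (SE 0.37) and NFKB2 at 1.98 (SE 0.21). Integrated stress response genes stood at 1.21 with 19 of 19 above 0 (CHAC1 3.14, SE 0.52; ASNS 2.34, SE 0.39), ERK output genes at 1.15 (ETV5 2.12, SE 0.26) and hypoxia genes at 0.53 (VEGFA 2.11, SE 0.33). Mitotic genes at -0.38, replication genes at -0.37, heat shock genes at -0.70 (HSPA8 -1.39, SE 0.22), cholesterol genes at -0.37 (LSS -0.93, SE 0.17) and replication-dependent histone genes at -0.54 (8 of 8 below 0) stood lower. Adjusted over the list alone, 11 of 17 NF-kB genes, 16 of 19 integrated stress response genes and 13 of 21 ERK output genes rose. Over all genes limma called 0 (smallest adjusted p 0.0787), 2078 had an unadjusted p under 0.05 where chance gives 716, and voom called 0. Camera called 9 of 39 lists, none of which held, at adjusted p between 0.216 and 0.555 with an estimated correlation. Fry called 1 list, the ERK output genes, for a move in one direction and 7 for change in either direction. This comparison and the knockdown comparison share the knockdown control libraries, so a chance deviation of those libraries enters both with opposite sign.

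The lines differed far more than any treatment. With 4 libraries per line, limma called 7195 of 14311 genes, 3533 higher in KYSE70 and 3662 higher in KYSE450, of which 3426 differed at least 2-fold. Of the named genes, the highest differences toward KYSE70 were those of the carboxylesterase gene CES1 at a log2 difference of 9.22 (SE 0.35) and the aldo-keto reductase gene AKR1B10 at 8.90 (SE 0.36), each with the sign in 4 of 4 line pairs, followed by UCHL1 at 8.88 (SE 0.30), SPP1 at 7.84 (SE 0.30) and OLFM1 at 6.95 (SE 0.17). IGFBP6 at -7.66 (SE 0.63), the keratin gene KRT17 at -7.17 (SE 0.16) and LCP1 at -7.16 (SE 0.18) were among those higher in KYSE450, beside RPS2P5 and RPS2P46, pseudogenes whose reads can be shared with RPS2. Genes high in 1 line were listed at trace level in libraries of the other: 10 markers of KYSE70 stood at a median of 0.0395% to 0.296% of their KYSE70 level in the KYSE450 libraries, and 18 markers of KYSE450 at 0.135% to 0.322% in the KYSE70 libraries. Of 18 NRF2 targets 16 passed over all genes and 17 adjusted over the list alone, with a median of 2.06 (FTL 3.31, SE 0.20). Epithelial junction genes were lower in KYSE70, at a median of -1.27; of 21 genes 16 passed as lower and 1 as higher, over all genes and adjusted over the list alone alike, among them the epithelial splicing regulators ESRP1 at -6.16 (SE 0.20) and ESRP2 at -4.72 (SE 0.17) and the transcription factor gene GRHL2 at -5.65 (SE 0.25). Ribosomal protein genes had a median of -0.55, with 25 of 42 passing over all genes and 25 adjusted over the list alone. Camera called these 3 lists, at adjusted p 0.230, 0.230 and 0.881 with an estimated correlation, and fry called 19 for a move in one direction and 36 for change in either direction.

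MMP10, NSUN2 and BPTF were to be reported in any case. The stromelysin gene MMP10 had a log2 fold change of 0.59 (SE 0.47) with overexpression and 0.87 (SE 0.47) with knockdown, adjusted p 1 and 0.448 in limma, and in KYSE450 it went from 31.4 to 79.7 FPKM and from 16.0 to 56.9 FPKM. In KYSE70 it stayed under 0.6 FPKM in all 4 libraries. NSUN2, which encodes an RNA methyltransferase, stood at -0.15 (SE 0.17) with overexpression and -0.32 (SE 0.17) with knockdown. The knockdown value came from -0.56 in KYSE70 and -0.08 in KYSE450. The chromatin remodeling gene BPTF stood at -0.02 (SE 0.13) with overexpression and 0.09 (SE 0.13) with knockdown, and none of these genes passed in limma.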

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

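The tests of whether RP11-242F24.1 is carried by the plasmid and both tests on the NF-kB genes were chosen after the result was seen; the other tests of this part were written before their values were known. The differences between the cell lines listed here were not tested, since a line has 1 library per group.

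RP11-242F24.1 (LINC01672 in GENCODE release 29, chromosome 1 from 6724637 to 6730012 in GRCh38) lay below the filter and is a signal outside the tested genes: it had 124 reads in the overexpression libraries, 24 in KYSE70 and 100 in KYSE450, 0 in their controls and 1 in the 6 other libraries. Against a floor of 3 reads over the control group it was at least 40.8-fold higher, and it was the only gene below the filter with 10 or more reads in both overexpression libraries and 0 in both controls. A rise of the whole region is argued against by the 16 tested genes within 500 kb, whose median log2 fold change was 0.028 (SD 0.189, -0.172 to 0.543). The nearest tested genes on each side, DNAJC11 and RP11-312B8.1, stood at -0.172 and -0.113. Read-through from a nearer transcript that was not tested stays open. Among the listed genes with coordinates in GENCODE release 29, 0 overlap it, which argues against reads shared with a listed overlapping gene. A candidate explanation is that the overexpression plasmid carries this gene; the knockdown controls hold 1 read, too few to test whether the knockdown lowers it, and no source used here gives it as NMR. That explanation therefore stays a hypothesis.

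Knockdown changed 768 genes at least 2-fold in KYSE70 and 136 in KYSE450, a ratio of 5.65. Depth is argued against as the whole cause, since libraries thinned to the shallowest gave a ratio of 5.41 (5.32 to 5.57 over 5 draws). So is a shift of the scale by a few abundant genes and the mitochondrial share, since 5.41 remained without the 50 top and the mitochondrial genes. That removal does not test whether the KYSE70 knockdown library differs in RNA quality. Gene length and GC content are argued against as the whole cause by a ratio of 4.39 once both trends were removed, although the KYSE70 count went from 768 to 566. A different response of the lines and any difference in handling of 1 library stay open and were not tested, with 1 library per line and group.

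NF-kB genes were lower with knockdown than with its control in both lines. If the knockdown controls alone had been shifted, the knockdown libraries would lie near the overexpression controls; their median difference was 0.336 in KYSE70 and 1.52 in KYSE450, with 14 of 17 genes above 0 in each, which decides neither way. If the genes followed the NMR level, overexpression would raise them; the medians were 0.143 in KYSE70 and -0.011 in KYSE450, which decides neither way as well. An effect of NMR and a shift between the lentiviral libraries cannot be told apart here, because each line has 1 knockdown and 1 control library.

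Between the lines, KYSE70 minus KYSE450, the log2 fold changes pointed in opposite directions for these genes and lists. With overexpression, the difference was -1.448 for MMP10, -0.977 for MMP1, -1.778 for SPRR1B, -1.538 for ASNS, -1.83 for CHAC1, 0.31 for NSUN2, 0.095 for BPTF, 0.745 for MT1F and 0.212 for SLC30A1. The list medians differed by -0.405 for integrated stress response genes and 0.577 for metallothioneins. With knockdown, it was -1.802 for MMP10, -1.572 for KLK10 and -0.515 for THY1, and the list medians differed by 0.717 for integrated stress response genes, -0.759 for ribosomal protein genes and 0.576 for mitochondrial messenger RNAs, which camera did not call. Dixon's criterion was passed in 0 of 26 groups of 4 values, 20 of them genes named for their difference between the lines, and with 4 values it passes only extreme gaps. The mitochondrial share of the KYSE70 knockdown library came to a ratio of 0.823, just under the critical value.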

How the results depend on the processing

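Voom, median-ratio scaling, quantile normalization, the robust prior, the correlation in each line alone or with a pseudocount of 0.1, the lists without knockdown replicate 1, the subtraction of a trace of the other line and the removal of GC and length trends were chosen after seeing the data; the others were planned. The edgeR and DESeq2 scalings that were planned for counts were not run, because the values are FPKM. Counts of called genes for the higher-against-lower NMR and the control comparisons were 0 in all 21 and 14 alternatives. For the cell line, 18 of 19 alternatives stayed within 1.5 times of 7195; asking for at least 2-fold gave 3426.

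For overexpression 15 of 18 alternatives also called 0 genes. The 4 libraries alone gave 12, and leaving out each library gave 0 to 3. For knockdown a pseudocount of 0.1 gave 3, voom 4 and the 4 libraries alone 37, and leaving out each library gave 580 to 4833, where the remaining pair is assumed to vary like the others; 11 of 18 gave 0. Pairing by cell line was part of the model: with no replicate block 0 genes were called for overexpression, 0 for knockdown and 0 for higher against lower NMR, and it changed no other call. With GC and length trends removed in the paired model, knockdown again gave 0 (smallest adjusted p 0.113).

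The correlation of overexpression with knockdown changes was 0.056 with a pseudocount of 0.1 and 0.017 in KYSE450 alone, against 0.101. At 1.5-fold, 7 genes changed the same way in both lines with overexpression and 177 with knockdown, against 0 and 21 at 2-fold; independent lists give 1.9 and 81.84 at 1.5-fold. At that fold 8 and 61 changed in opposite directions, where independent lists give 1.85 and 90.97. With an estimated correlation camera called 0 lists in each of the 5 comparisons; fry called 0 for overexpression, 0 for knockdown, 0 for higher against lower NMR, 19 for the lines and 1 for the controls. Without knockdown replicate 1 the list calls for knockdown changed, but they then rest on the KYSE450 pair alone, which is assumed to vary like the overexpression pairs. For higher against lower NMR camera called 15 lists without that library.

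Directions turned for these values, none of which passed over all genes; the cause was not tested, beyond the fewer libraries where a line was left out. Lowest and highest values without 1 library are given as ranges.

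List medians ranged from -0.043 to 0.362 for integrated stress response genes and from -0.509 to 0.068 for metallothioneins with overexpression. With knockdown they ranged from -0.687 to 0.03 for integrated stress response genes, from -0.655 to 0.104 for ribosomal protein genes and from -0.248 to 0.328 for mitochondrial messenger RNAs. MMP10 ranged from -0.134 to 1.314 with overexpression, from -0.032 to 1.77 with knockdown and from -0.624 to 0.404 for higher against lower NMR. NSUN2 ranged from -0.302 to 0.008 with overexpression and from -0.07 to 0.216 for higher against lower NMR. With overexpression BPTF ranged from -0.067 to 0.028, MMP1 from -0.062 to 0.915, SPRR1B from -0.287 to 1.491, ASNS from -0.058 to 1.48, CHAC1 from -0.001 to 1.829, MT1F from -0.677 to 0.068 and SLC30A1 from -0.143 to 0.069. With knockdown KLK10 ranged from -1.451 to 0.121 and THY1 from -0.318 to 0.197. In other settings, BPTF was 0.004 with overexpression under quantile normalization and, with trends removed, -0.051 with knockdown and 0.006 for higher against lower NMR; THY1 with knockdown was 0.314 with a pseudocount of 0.1 and 0.02 with trends removed. Depth limits mainly genes near 1 FPKM, where the pseudocount shrinks the fold changes.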

Other observations

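The genes named in the first paragraphs of this part were chosen after their values were seen, from counts of genes changed at least 2-fold in single pairs, without a test within the pair. The subtraction of a trace of the other line was also chosen after the values were seen; the splits of the libraries were planned.

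With knockdown, 8 genes stood at least 2-fold from the knockdown control in opposite directions in the lines. TXNIP and ARRDC4, genes of arrestin-domain proteins, stood at -2.14 and -1.20 in KYSE70 and at 3.28 and 1.97 in KYSE450. TSC22D3, a glucocorticoid-induced gene, stood at 1.18 in KYSE70 and -1.82 in KYSE450, DDIT3, a transcription factor gene of the integrated stress response, at 1.001 and -1.63, and PHLDA1 at 1.09 and -1.35. The small structured RNA RN7SL1 stood at -2.33 and 1.16. In KYSE70, TXNIP stood at 55.2 FPKM in the overexpression control, 442 in the knockdown control and 99.6 with knockdown. In KYSE450 it stood at 258, 13.15 and 137. ARRDC4 likewise ran back toward the overexpression control in both lines. For TXNIP and ARRDC4 a response cannot be told apart from a deviation of the knockdown control. TSC22D3, DDIT3 and PHLDA1 in KYSE70, and RN7SL1 in both lines, stood further from the overexpression control with knockdown.

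Within KYSE450, 9 genes changed 2-fold in opposite directions with overexpression and knockdown, where independent lists give 0.2, and 4 changed the same way, 3 higher where 0.21 are given and 1 lower where 0.04 are given. The stress response genes CHAC1 and STC2 stood at 1.83 and 1.13 with overexpression and at -1.72 and -1.53 with knockdown. TSC22D3 stood at 1.17 and -1.82 and WNT11 at -1.16 and 1.59. In FPKM, CHAC1 stood at 2.24 in the KYSE450 overexpression control, 47.6 in the knockdown control and 13.75 with knockdown. In the same order STC2 stood at 14.9, 254 and 87.4, TSC22D3 at 12.8, 61.4 and 16.7, and WNT11 at 17.05, 1.305 and 5.95. These knockdown changes ran toward the overexpression control, so a response cannot be told apart from a deviation of the knockdown control. MMP10, IGFBP5 and GSN were higher with both, GSN at 1.03 and 1.01. Within KYSE70, 10 genes changed the same way, 5 higher where 0.23 are given and 5 lower where 0.44 are given, and 3 in opposite directions, where 0.72 are given. At 1.5-fold, 35 genes changed the same way in KYSE450, where independent lists give 10, and 41 in opposite directions, where they give 7.16. In KYSE70 the counts were 40, where 18.79 are given, and 24, where 18.94 are given. In KYSE70 the protease inhibitor genes PI3 and SLPI stood at -1.49 and -1.08 with overexpression and at -2.87 and -2.07 with knockdown, and the receptor gene NRP1 at 1.24 and 1.87. The pairs share no library, and whether the lines differ was not tested.

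Of the 9 opposite changes in KYSE450, AKR1B10 and CES1 were genes of KYSE70 at trace level. AKR1B10 stood at 3.58 FPKM in the KYSE450 overexpression control and 1.06 with overexpression, and at 1.01 in the knockdown control and 5.72 with knockdown, against 1423 to 1744 in KYSE70. CES1 stood at 1.24, 0, 0 and 2.05 FPKM in the same order and UCHL1, another KYSE70 gene, at 1.14, 0.073, 0.14 and 1.60. Over 10 such markers the median share of the KYSE70 level was 0.246%, 0.0541%, 0.0395% and 0.296%. With this share subtracted, each marker's own taken from the others, AKR1B10 went to 0.35 and 0.25 and CES1 to 0 and 0, and 7 of the 9 opposite changes were left. All 21 genes that changed the same way in both lines with knockdown kept their 2-fold change.

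Other splits of the libraries were fitted in the same way. Of the 35 splits into 4 and 4 libraries, 1, the split by cell line, called as many as 7195 genes, and the highest other split called 10. All other splits mix the lines, whose difference then enters the spread, so their low counts were set in advance. The splits therefore do not test chance, and the labels do not say that the 4 libraries of a line are separate cultures. For higher against lower NMR, 5 of the 8 ways to part all 4 pairs, the real one included, gave as many as 422 genes at an unadjusted p under 0.05, and the highest other gave 688; 8 splits are too few for a share under 0.05.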
